A study of Homo sapiens with 8 samples.

How the data were processed

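RNA was measured in H1299, an established human lung carcinoma line without p53, after transfection of plasmids expressing GFP, p53, p47 or both p53 and p47, the last named 14A in the labels. Per the labels' protocols, 500 ng of plasmid was transfected 14 hours after seeding, cells were harvested 48 hours later, and 500 ng of total RNA was copied from an oligo-dT primer and labelled with Cy3. Each of the 4 groups had 2 samples, numbered by set in the labels, which do not say what a set is. Nothing says that the samples of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

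Per the file headers, the arrays were 1-colour Agilent arrays of design 039494 with 60-base probes and were read with Feature Extraction 11.5.1.1 under the protocol GE1_1105_Oct12, with probe coordinates on the human build hg19. The processed signal that the authors deposited is a linear intensity after that program's background subtraction. The labels credit the processing to Agilent Feature Extraction, and other steps are not given in the sources used here. A table of the whole series holds the authors' log2 values. Set against the scanner values, each of its columns followed log2 processed signal with a Pearson r across probes of 0.9997 to 0.9999, with medians of -4.02 to -3.66 and 75th percentiles of 0.00578 to 0.00867, and it served as an alternative. Its scale and direction were therefore settled from the data, while its exact centring stays unstated. All 8 arrays lay on 1 slide and were scanned in 1 run, so slide and scan gave no batches. The GFP and p53 arrays lay in slide row 1 and the p47 and 14A arrays in slide row 2. Row and group therefore cannot be told apart outside p53 against GFP and 14A against p47. The GFP and p47 arrays lay in slide columns 1 and 2 and the p53 and 14A arrays in columns 3 and 4. Column and group therefore cannot be told apart outside p47 against GFP and 14A against p53. Each comparison thus crosses rows, columns or both.

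Each array held 58717 spots other than controls, for 50599 probes. Control spots and spots that the program marked as outliers (262 to 633 per array) were left out, and spots of the same probe were averaged. The log2 processed signal was scaled by subtracting each array's 75th percentile. A probe counted as well above background on an array if at least 50% of its spots did by the program's own mark, and was kept if it was so on both arrays of at least 1 group, which left 30583 probes. A transcript seen in 1 group only could thus be kept through that group, which favours rises there. Of the 50599 probes, 28174 were named through a RefSeq accession, 2618 through a current symbol, 620 through a synonym of a single gene, and 19187 kept the file's name, so that 5007 names differ from the file's. Each gene was represented by its kept probe with the highest mean over all arrays, and 5552 of the 22962 genes tested had more than 1 kept probe. The part of the transcript that a probe matches was not analysed here. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.273. No spot was saturated.

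The 6 comparisons between groups were fitted with limma 3.58.1 in R 4.3.3 on all 8 arrays together (lmFit, then eBayes with an intensity trend, 4 residual and 4.14 prior degrees of freedom), with Benjamini-Hochberg adjustment over 22962 genes and a threshold of 0.05. A log2 fold change is followed by its standard error (SE), and levels are means of scaled log2 signal with the SD of 2 arrays. Where no array of the dimmer group was well above background, the fold is given as a lower bound. It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background, and the fitted log2 value beside it is no bound. In a test on simulated data for p53 against GFP, with 200 of 22962 genes changed, 16.5% of 2-fold, 80.5% of 4-fold, 96.6% of 8-fold and 99% of 16-fold changes were recovered over 20 draws, and 6.76% of calls were false. There, lists shifted by 0.5 log2 units all reached an unadjusted p under 0.05, as did 1.9% of unshifted lists. Genes were drawn independently, so that rate does not cover lists whose genes vary together. The correlation estimated from the arrays reached 0.567, for cytosolic ribosomal proteins.

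Gene lists were tested against the other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over 132 tests (22 lists in 6 comparisons). They covered 3 sets of p53 target genes, p53 family and regulators, G2 and mitosis, G1/S and DNA replication, the unfolded protein and integrated stress response, interferon, NF-kB and inflammatory genes, heat shock, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, epithelial, mesenchymal, fibroblast and leukocyte markers, immediate early genes, cytosolic ribosomal proteins, replication-dependent histones, housekeeping genes and the insulin-like growth factor pathway. With a correlation estimated from the arrays, 0 of the 132 tests passed after adjustment, against 32 with the preset value, and 10 had an unadjusted p under 0.05. That loss does not come from the correlations alone. For the apoptosis targets in p53 against GFP the estimate was 0.00374, under the preset 0.01, yet the unadjusted camera p rose from 4.93e-05 to 0.0121. A high p with an estimated correlation therefore does not by itself show that a list's genes vary together. The test limma calls fry, which asks whether the genes of a list move on balance the same way, also passed 0. The p-values with an estimated correlation in the results are adjusted unless called unadjusted. In 40 list tests the direction of the test differed in sign from the list's median or mean, and none of these passed with the preset value. Overlaps of calls between comparisons that share the GFP arrays were set beside 100 simulations of unchanged groups against them. These simulations, and the values given for chance, treat the arrays as independent and leave out any variation shared by arrays of a set. Arrays with the same set number deviated together, with correlations of 0.26 to 0.544 between the set 1 deviations of the 6 pairs of groups, and the first principal component separated the sets. The set numbers come from the labels, and with 2 arrays per group these correlations rest on only 4 independent deviations. The fit without a block was kept as fixed beforehand, and blocked values stand beside the results they change, a placement chosen after the calls of both fits were known.

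The groups, lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names CDKN1A, MDM2, BAX, BBC3, GADD45A, SFN, FAS, TP53I3, GDF15 and IGF1R throughout (1 further gene, which was tested with the others and enters the counts, is not reported here); the 10 largest rises and 10 largest falls per comparison among called genes whose groups do not overlap and that have a gene symbol (LOC, long noncoding RNA, XLOC, ENST, open reading frame and accession names left out), at most 20 being printed; up to 4 members with the smallest adjusted p of each list that passes or has a called member; the 5 genes with the smallest p where fewer than 5 pass; and the 5 genes with the largest difference among those called in opposite directions. The alternatives were normexp background correction with an offset of 50, quantile and median scaling, the authors' log2 table, no filter or a stricter filter on dim probes, the mean of a gene's probes, only the arrays compared, no intensity trend, robust empirical Bayes, a block for the replicate number, a 2-fold minimum, and each array left out. Median scaling moved the median log2 fold change of all genes by over 0.1 in 3 comparisons, from 0.0585 to -0.0781 in 14A against GFP, from -0.0476 to 0.0871 in p47 against p53 and from 0.0643 to -0.146 in 14A against p47. The list test compares a list with the other genes, and no list that passed turned direction under either scaling. Files were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.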

Results

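Transcript levels were compared in H1299 cells that received a plasmid for GFP, for p53, for p47, or for p53 and p47 together (14A). H1299 is a human lung carcinoma line that lacks p53, the tumour suppressor and transcription factor, so that the transfected plasmid is the source of the protein. p47 is a form of p53 that lacks the amino-terminal end, with part of its transactivation domain. The labels describe the series as p53 alone, p47 alone or both, and the comparisons ask how each plasmid changed the cells' transcripts. Between 34758 and 37477 of 58717 spots per array (59.2% to 63.8%) were well above background. Across genes, which are not independent replicates, the replicate arrays correlated with an r of 0.990 for GFP, 0.985 for p53, 0.989 for p47 and 0.977 for 14A, against 0.977 to 0.992 between arrays of different groups. The first principal component held 35.7% of the variance and separated the arrays by set number rather than by plasmid, with 14A replicate 1 at its end (-65.3).

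With p53 alone 7 transcripts were higher than with GFP, 4 of which were not well above background in control cells, and PROC was lower. INPP5D, an inositol phosphatase known from blood cells (chromosome 2, 234116417 to 234116476), was at least 15.7-fold higher than with GFP (log2 5.90, SE 0.35, adjusted p = 0.00161). CYP4F2 and CYP4F3, fatty acid and leukotriene hydroxylases (chromosome 19, 15988846 to 15988905 and 15770754 to 15770813), were at least 12.5-fold (adjusted p = 0.00167) and 5.66-fold (adjusted p = 0.00361) higher. As near-identical paralogs, their probes may share signal, so the pair is uncertain. FDXR, the mitochondrial ferredoxin reductase (chromosome 17, 72858650 to 72858709), rose from 4.26 ± 0.10 to 5.82 ± 0.02 (SD, n = 2; log2 1.56, adjusted p = 0.0312), and SH2D2A, an adaptor of T-cell signalling, rose by 3.05 (adjusted p = 0.00361). PROC, the precursor of the anticoagulant protein C, fell by 4.92 (SE 0.26, adjusted p = 0.00126), from 0.74 ± 0.15 to -4.18 ± 0.17.

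Of 22962 genes, 9 passed against GFP, 7 higher and 2 lower, all by at least 2-fold. With a block for the set 47 passed, 26 higher and 21 lower, among them these 9. Named after their values were seen, LOC100129931 (at least 7.29-fold higher) and the unnamed probe A_33_P3312754 (-3.63) were among them. Quantile scaling gave 8 higher and 4 lower, normexp 6 and 6, and robust empirical Bayes 8 and 7, so the excess of rises depended on the setting. The classical p53 targets had positive values that did not pass singly. GDF15, a stress-induced growth factor, stood at 2.10 (SE 0.26, adjusted p = 0.0630), BTG2, an antiproliferative gene, at 2.63 (adjusted p = 0.111), MDM2, the ubiquitin ligase of p53, at 1.19 (adjusted p = 0.161), TP53I3 at 1.08 (adjusted p = 0.412) and CDKN1A, the cell cycle inhibitor p21, at 0.96 (interval 0.21 to 1.71). FAS gave 0.52, BAX 0.46, GADD45A 0.38, BBC3 0.33, IGF1R 0.05 and SFN 0.01, and without p53 replicate 2 GADD45A gave -0.07 and BBC3 0.10. With the block for the set GDF15 (adjusted p = 0.0109), BTG2 (0.0130), MDM2 (0.0428), the listed target VWCE (0.0159, against 0.0788) and HSPA6 (0.0106) passed.

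As lists, the p53 targets rose relative to other genes. The 32 measured targets in DNA repair and metabolism had a median of 0.296 (adjusted p = 1.28e-09), with 29 positive, 2 called higher (INPP5D and FDXR) and 6 higher adjusted over the list alone. The adjusted p = 0.187 with an estimated correlation. The 29 targets in cell cycle arrest and feedback had a median of 0.266 (adjusted p = 1.02e-04), with 0 called and 5 higher adjusted over the list alone, and the adjusted p = 0.552 with an estimated correlation. The 28 apoptosis targets had a median of 0.273 (adjusted p = 5.00e-04), with 0 called and 2 adjusted over the list alone. TP53I3 at 1.08 and PIDD1 at 1.05 were among its members, and the adjusted p = 0.319 with an estimated correlation. Without p53 replicate 2 the arrest and apoptosis lists no longer passed (adjusted p = 0.155 and 0.117). Heat shock genes were lower, with 12 of 18 negative and a median of -0.12 (adjusted p = 3.58e-04, and adjusted p = 0.700 with an estimated correlation). HSPA6 stood at -3.17 (adjusted p = 0.0630), HSPA1A at -0.94, its near-identical copy HSPA1B at -0.96 and DNAJB1 at -0.42, and the list did not pass without GFP replicate 1 (adjusted p = 0.0969). The 13 leukocyte markers were higher with a median of 0.316 (adjusted p = 0.0335, and adjusted p = 0.533 with an estimated correlation), with CD79A at 0.72, CD3D at 0.69 and CD3E at -0.40, which did not pass, and 11 of them were already well above background on both GFP arrays. The value of CD79A rested on p53 replicate 1, with 2.39 and 0.724 on the p53 arrays against 0.949 and 0.732 with GFP. The leukocyte list was lost without GFP replicate 1 (adjusted p = 0.416), p53 replicate 1 (0.218) or p53 replicate 2 (0.0746), and under quantile scaling (0.0528), normexp (0.0704), no filter (0.0583) and the mean of probes (0.0825). Interferon response genes, with 22 of 28 negative and a median of -0.09, passed with the block for the set (adjusted p = 0.0161) and not without it (0.0614), where it gave 0.977 without GFP replicate 2 and 0.931 without p53 replicate 1. The count of 9 genes became 4 without GFP replicate 2, 3 without p53 replicate 1 and 2 without p53 replicate 2. PROC and INPP5D were called whichever array was left out, and FDXR in none of those fits.

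**Figure D1:**
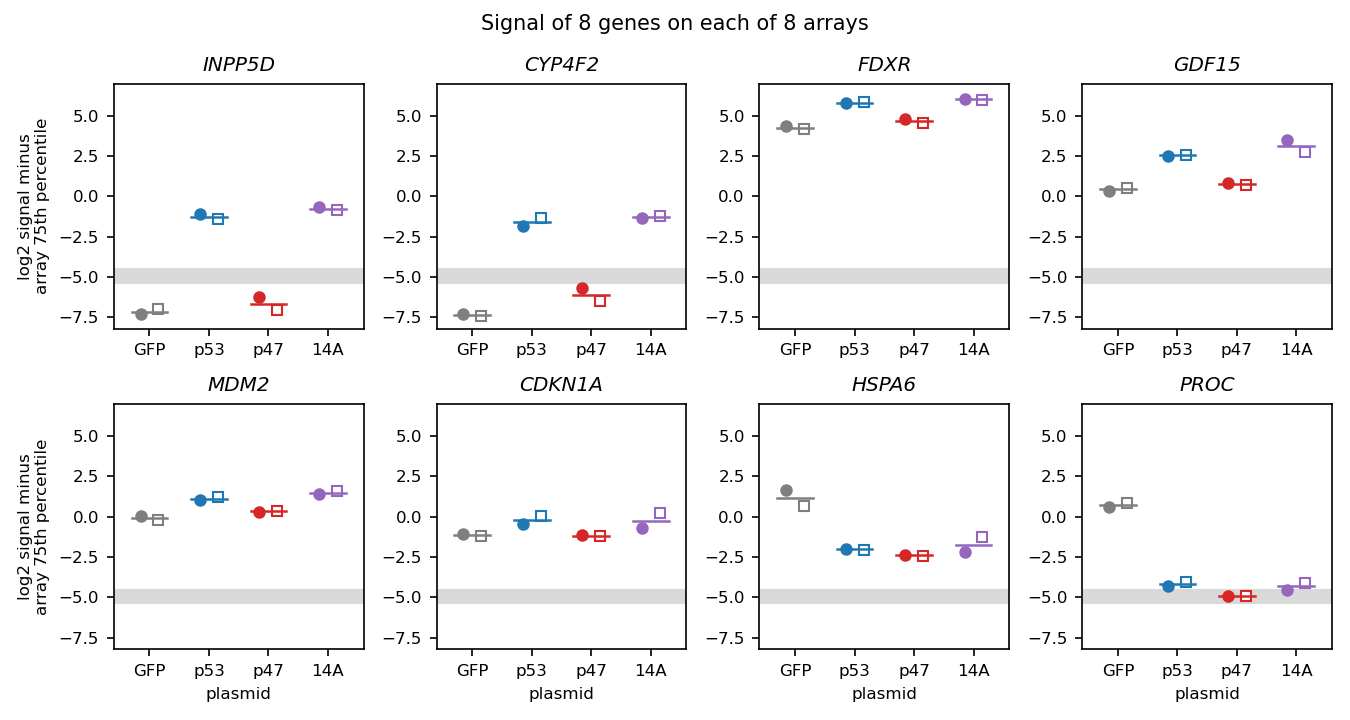
Each panel shows log2 signal minus the array's 75th percentile for 1 gene on the 8 arrays, with filled circles for replicate 1, open squares for replicate 2 and a line at the mean of 2. The grey band spans the arrays' lowest signal among probes well above background. INPP5D and CYP4F2 lay above the band with p53 and 14A and below it with GFP and p47, while PROC fell from 0.74 with GFP to between -4.91 and -4.18 with the other plasmids.

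With p47 alone PROC and HSPA6 were lower than with GFP, and no listed p53 target gene passed singly. Both were also lower than GFP with p53, where HSPA6 did not pass, and with 14A. PROC was at least 47.8-fold lower than with GFP (log2 -5.65, SE 0.26, adjusted p = 4.19e-04). HSPA6, a stress-induced chaperone of the HSP70 family (chromosome 1, 161496158 to 161496217), fell by 3.55 (SE 0.38, adjusted p = 0.0269), from 1.16 ± 0.68 to -2.39 ± 0.05 (SD, n = 2), and its second probe gave -1.83. SH2D2A rose by 2.94 (adjusted p = 0.0106), close to its rise with p53, and HRH2, a histamine receptor, rose by 2.97 (adjusted p = 0.0487). HRH2 was not particular to p47 (-0.714 and -0.711 per array). It stood at -1.13 and -0.726 with p53 and -1.68 and -0.555 with 14A, against -3.497 and -3.874 with GFP. Values of the targets that did not pass were 0.49 for TP53I3, 0.41 for MDM2, 0.40 for FDXR, 0.33 for GDF15, 0.28 for FAS, 0.08 for GADD45A, -0.02 for CDKN1A, -0.06 for IGF1R, -0.09 for SFN, -0.35 for BBC3 and -0.64 for BAX. The last 2 rested on p47 replicate 2, without which BBC3 gave 0.01 and BAX 0.16. Without that array TP53I3 gave 0.31, FAS 0.05 and GADD45A -0.01, and without p47 replicate 1 they gave 0.67, 0.51 and 0.18.

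In all, 25 genes passed for p47 against GFP, 9 higher and 16 lower. With a block for the set 66 passed, 21 higher and 45 lower, among them these 25. Quantile scaling gave 11 higher and 6 lower and median scaling 10 and 4, while normexp gave 3 and 23, so the balance of rises and falls depended on the setting. Of the 9 higher, 6 were not well above background on either GFP array, and 5 were transcripts without a gene symbol. Other falls included DEFB128, a defensin (at least 2.54-fold, adjusted p = 0.0487), the pseudogene NPAP1P9 (-2.95, adjusted p = 0.0319), KALRN, a guanine nucleotide exchange factor (-2.95, adjusted p = 0.0487), and F7, a clotting factor (-2.76, adjusted p = 0.0487), which was well above background on 1 of 2 p47 arrays. KALRN and F7 were measured with probes rich in CA repeats, as were 8 of the 16 falls, against 0.536% of the genes tested. Their values in p53 against GFP were -1.95 and -1.86, and their differences between p47 and p53 (-1.01 and -0.90) did not pass. Named after their values were seen, LINC00955 (-3.30), AK127601 (-2.67), LOC553137 (-2.12) and C8orf58 (-1.62) were also among the falls, and the other probe of C8orf58 gave 0.16. These transcripts, NPAP1P9, KALRN and F7 were also lower than with GFP on both p53 arrays and both 14A arrays. Their falls were therefore not particular to p47. LINC00955 stood at -0.884 and -0.901 with GFP, -2.84 and -2.56 with p53, and -3.59 and -2.33 with 14A.

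Among the lists, replication-dependent histone genes were higher with p47, 26 of 27 being positive with a median of 0.289 (adjusted p = 8.10e-06), with H2AC4 at 0.57 and H4C8 at 0.56. RNA was copied from an oligo-dT primer, so histone transcripts that the primer does not copy went unmeasured, here and in the other comparisons. Nuclear genes of oxidative phosphorylation were higher, also with 26 of 27 positive, a median of 0.213 (adjusted p = 2.77e-04) and ATP5PF at 0.58 and COX4I1 at 0.46. No member of either list passed, over all genes or adjusted over the list alone, and the adjusted p = 0.934 with an estimated correlation for both. Heat shock genes were lower, with 17 of 18 negative, a median of -0.19 (adjusted p = 6.24e-04), 1 called and 3 adjusted over the list alone. For that list the adjusted p = 0.731 with an estimated correlation, HSPA1B stood at -1.23 and HSPA1A at -1.03, and the adjusted p was 0.0912 without GFP replicate 1. Of the p53 target lists, DNA repair and metabolism was higher by a median of 0.101 (adjusted p = 0.0250, and adjusted p = 0.533 with an estimated correlation), with 0 called and VWCE at 0.83, KITLG at 0.57 and ASCC3 at 0.42. It was lost under median scaling (adjusted p = 0.0633), without a filter (0.103), without GFP replicate 1 (0.0969) and without p47 replicate 1 (0.227). The arrest and apoptosis lists did not pass (adjusted p = 0.442 and 0.524). The 25 calls fell to 5 and 2 without GFP replicates 1 and 2, to 3 without either p53 array, and to 2 and 3 without p47 replicates 1 and 2. PROC was the only call kept whichever array was left out, and HSPA6 was lost without any 1 of the GFP, p53 and p47 arrays.

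All 7 transcripts that were higher with p53 than with GFP were also higher with 14A, and GDF15, MDM2 and BTG2 passed as well. INPP5D was at least 22.2-fold higher than with GFP (log2 6.40, SE 0.35, adjusted p = 8.40e-04), CYP4F2 at least 15.7-fold (adjusted p = 0.00108) and CYP4F3 at least 7.22-fold (adjusted p = 0.00254). GDF15 rose by 2.69 (SE 0.26, adjusted p = 0.0139), from 0.43 ± 0.14 to 3.12 ± 0.56 (SD, n = 2), FDXR by 1.76 (adjusted p = 0.0125), MDM2 by 1.56 (SE 0.19, adjusted p = 0.0322) and BTG2 by 2.87 (adjusted p = 0.0493). PROC fell by 5.04 (adjusted p = 8.40e-04), HSPA6 by 2.89 (adjusted p = 0.0466) and NPAP1P9 by 2.74 (adjusted p = 0.0318). For none of these genes did the difference between 14A and p53 pass. The calls of MDM2, BTG2 and HSPA6 were lost whichever of the 8 arrays was left out, that of GDF15 without either GFP array, and that of FDXR without any 1 of the GFP and 14A arrays. BTG2 was called in 4 of the 14 other settings.

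Of the 31 genes that passed for 14A against GFP, 25 were higher and 6 lower, against 15 and 11 with normexp, and 14 of the 25 were not well above background on either GFP array. Further rises were KLHL30 (at least 8.71-fold), PLK5, a polo-like kinase family member (at least 7.75-fold), NSG1 (at least 6.08-fold), OR51B5 (at least 5.16-fold), SCN3B, a sodium channel subunit (3.74, well above background on 1 of 2 GFP arrays), and EGR2, an early-response transcription factor (3.55, adjusted p = 0.0466) and the only called member of the 16 immediate early genes, of which JUNB stood at -0.83. OR51B5 was not particular to 14A (-3.30 and -2.41 per array). It stood at -3.23 and -2.55 with p53 and -3.22 and -2.97 with p47, against -7.14 and -5.94 with GFP. KLHL30, PLK5, NSG1, SCN3B and EGR2 were also higher than GFP on both p53 arrays, though not called there in the fit without a block. SCN3B stood at -2.29 and -2.35 with p53, against -4.31 and -5.20 with GFP. EGR2 stood at -1.53 and -0.539 with p53, against -3.55 and -3.19 with GFP. VWCE, a listed p53 target, rose by 3.05 (adjusted p = 0.0175), while its other probe gave -0.27. Not passing were ASCC3 at 1.45 (adjusted p = 0.0583), TP53I3 at 1.37 (adjusted p = 0.139), PIDD1 at 1.29, CDKN1A at 0.91 (adjusted p = 0.848), FAS at 0.74, GADD45A at 0.49, BBC3 at 0.29, BAX at 0.27, IGF1R at 0.05 and SFN at -0.05. Without 14A replicate 2 CDKN1A gave 0.42 and GADD45A 0.18, and without 14A replicate 1 BBC3 and BAX gave 0.02 each. With a block for the set 81 genes passed, 60 higher and 21 lower, among them 30 of the 31, and ASCC3 (adjusted p = 0.0118), TP53I3 (0.0194) and PIDD1 (0.0222) were called.

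The p53 target lists rose with 14A. DNA repair and metabolism had a median of 0.270 (adjusted p = 3.11e-08), 3 called of 32 (INPP5D, FDXR and VWCE) and 7 adjusted over the list alone. Arrest and feedback had a median of 0.322 (adjusted p = 4.86e-05), 3 called of 29 (GDF15, MDM2 and BTG2) and 9 higher and 1 lower adjusted over the list alone, and apoptosis a median of 0.238 (adjusted p = 0.00235), with 0 called of 28 and 3 adjusted over the list alone. The adjusted p = 0.187, 0.533 and 0.336 with an estimated correlation, in that order. Without 14A replicate 2, arrest and apoptosis no longer passed (adjusted p = 0.0738 and 0.204). Histone genes were higher (median 0.336, adjusted p = 0.00383), with H4C8 at 0.76, with an adjusted p of 0.232 without GFP replicate 1 and 0.169 without 14A replicate 1. Leukocyte markers were higher (median 0.400, adjusted p = 0.00963), including MS4A1, at least 3.26-fold higher but not passing (adjusted p = 0.105), and CD68 at -0.40, with 1 member adjusted over the list alone. That list was lost without GFP replicate 1 (0.160) or 14A replicate 2 (0.399), under normexp (0.103) and with the strict filter (0.113). Heat shock genes were lower (median -0.11, adjusted p = 0.00141, 1 called of 18), as were glycolysis and hypoxia genes (median -0.12, adjusted p = 0.0250), with SLC2A3 at -0.82, PKM at -0.46 and ADM at 0.50, and cholesterol synthesis genes (median -0.16, adjusted p = 0.0432), with MSMO1 at -0.96 and HSD17B7 at 0.56. For these 5 lists the adjusted p = 0.934 (histone), 0.423 (leukocyte), 0.789 (heat shock), 0.934 (glycolysis) and 0.934 (cholesterol) with an estimated correlation. The last 3 were lost without GFP replicate 1 (adjusted p = 0.0912, 0.181 and 0.347) and without 14A replicate 2 (0.105, 0.736 and 0.812), and cholesterol with the mean of probes (0.0563).

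The 14A arrays differed more from each other than those of other groups, with an SD of their difference across genes of 0.708 against 0.473 to 0.575. Over 2374 transcripts with 2 probes, 14A replicate 1 was lower than replicate 2 at the 5′ probe relative to the 3′ probe by a median of -0.24, against -0.11 to 0.10 in the other groups. The 31 calls became 7 without 14A replicate 1, 11 without 14A replicate 2, 12 and 5 without GFP replicates 1 and 2, 16 and 14 without p53 replicates 1 and 2, and 19 without either p47 array. PROC, INPP5D, CYP4F2 and CYP4F3 were called whichever array was left out.

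**Figure D2:**
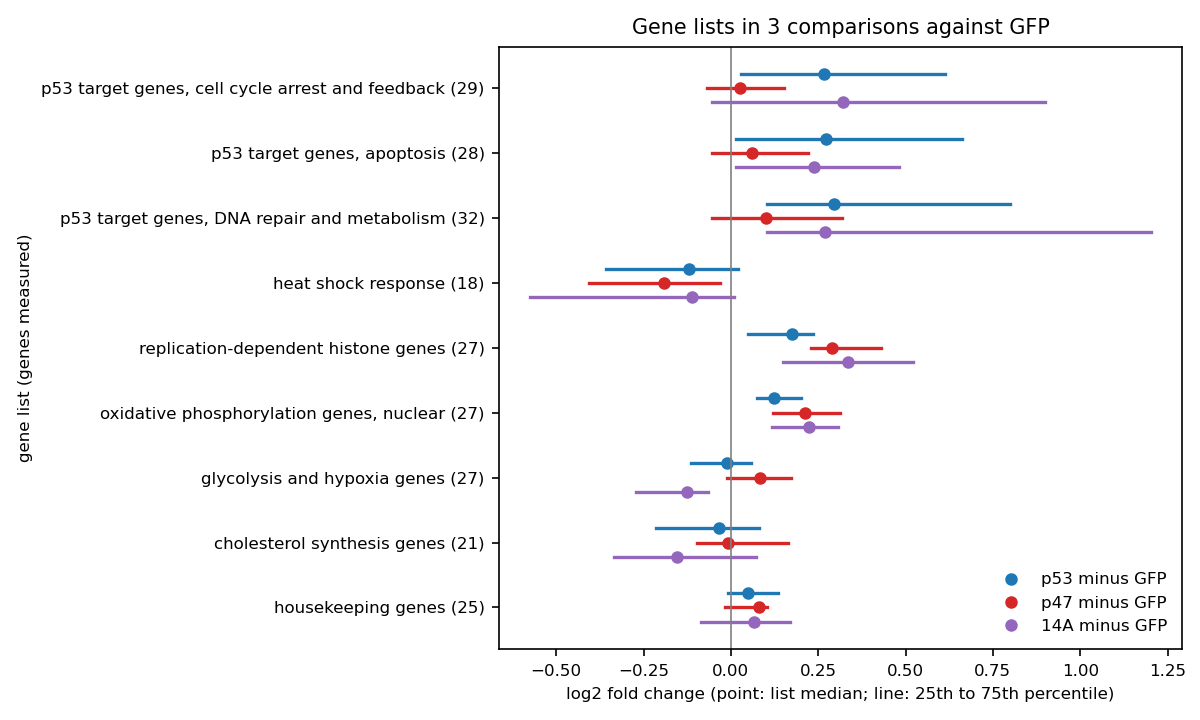
Median log2 fold change against GFP (points) of the genes in 9 lists, with lines from the 25th to the 75th percentile of the list's genes, for p53, p47 and 14A. The 3 p53 target lists had medians of 0.238 to 0.322 with p53 and 14A and of 0.027 to 0.101 with p47.

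Set directly against p53, p47 gave lower INPP5D and CYP4F2. INPP5D was at least 12-fold lower (log2 -5.40, SE 0.35, adjusted p = 0.00652) and CYP4F2 at least 9.58-fold lower (-4.52, adjusted p = 0.0165). These were the only 2 genes that passed, both lower, while quantile scaling gave 5 higher and 2 lower and median scaling 4 higher and 2 lower. The next by p did not pass: the transcripts XLOC_009451 and XLOC_l2_010936, at least 5.37-fold and 4.63-fold higher, and CYP4F3, at least 4.35-fold lower, each with an adjusted p of 0.0651. XLOC_009451 and XLOC_l2_010936 were well above background on the 2 p47 arrays only and were kept through them. GDF15 stood at -1.77 (SE 0.26, adjusted p = 0.213), FDXR at -1.16 (adjusted p = 0.2), BAX at -1.11, CDKN1A at -0.98, MDM2 at -0.78, BBC3 at -0.68, TP53I3 at -0.59, GADD45A at -0.29, FAS at -0.24, IGF1R at -0.11 and SFN at -0.10, none of which passed. Without p47 replicate 2 BAX gave -0.30 and BBC3 -0.32, and without p53 replicate 2 GADD45A gave 0.15, IGF1R 0.28 and SFN 0.35. FAS gave -0.01 without p47 replicate 1 and -0.47 without p47 replicate 2.

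The p53 target lists were lower with p47 than with p53. DNA repair and metabolism had a median of -0.24 with 30 of 32 negative, 1 called (adjusted p = 8.25e-07), arrest and feedback -0.23 with 22 of 29 negative, 0 called (adjusted p = 2.77e-04), and apoptosis -0.24 with 20 of 28 negative, 0 called (adjusted p = 0.00216). Adjusted over the list alone, 3, 3 and 0 members were lower. The adjusted p = 0.187, 0.596 and 0.336 with an estimated correlation. Without p53 replicate 2, arrest and apoptosis no longer passed (adjusted p = 0.252 and 0.177). Histone genes (median 0.105, adjusted p = 0.00900), interferon response genes (0.0894, adjusted p = 0.0103, with OAS1 at 0.71 and MX2 at -0.34), glycolysis and hypoxia genes (0.0674, adjusted p = 0.0250, PFKFB4 at 0.51 and ADM at -0.23) and oxidative phosphorylation genes (0.0845, adjusted p = 0.0269, SDHD at 0.24 and ATP5MC1 at -0.12) were higher, with 0 members called in each, and the adjusted p = 0.934 with an estimated correlation for all 4. OAS1 was well above background on 5 of the 8 arrays. Each of these 4 lists was lost without single arrays. Without p53 replicate 2 the histone and oxidative phosphorylation lists turned direction (adjusted p = 0.679 and 0.755) and glycolysis gave 0.452, and without p53 replicate 1 interferon gave 0.830. Without p47 replicate 2 the histone, interferon and oxidative phosphorylation lists gave 0.574, 0.336 and 0.292, and without p47 replicate 1 glycolysis gave 0.346. Without a filter on dim probes glycolysis, interferon and oxidative phosphorylation gave 0.135, 0.238 and 0.110, interferon gave 0.0743 under median scaling, and oxidative phosphorylation 0.0519 under quantile scaling. INPP5D lost its call without p53 replicate 1 or p53 replicate 2, and CYP4F2 without either p53 array, p47 replicate 2 or either 14A array.

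Between 14A and p53, no gene passed. By limma 350 genes had an unadjusted p under 0.05, where chance gives 1148.1 for independent arrays. That value leaves out any variation shared by arrays of a set. The other settings gave 0 to 6 calls. A count under chance was not particular to this comparison. Against GFP it was 659 for p53 and 784 for p47, and it was 483 for p47 against p53 and 759 for 14A against p47. Only 14A against GFP lay above chance (1208). The 5 genes with the smallest p, none passing, were the transcripts XLOC_005433 and XLOC_l2_009301, at least 8.82-fold and 5.56-fold higher with 14A (adjusted p = 0.0833 for both), XLOC_010284 (at least 4.73-fold), XLOC_006905 (at least 3.74-fold) and ENST00000390551 (at least 2.59-fold). All 5 were well above background on the 2 14A arrays only and were kept by the filter through them. GDF15 differed by 0.58 (interval -0.02 to 1.19), MDM2 by 0.37 (-0.07 to 0.82), TP53I3 by 0.29, FAS by 0.22, GADD45A by 0.11, BBC3 by -0.04, CDKN1A by -0.05 (-0.80 to 0.69), SFN by -0.06, BAX by -0.19 and IGF1R by -0.00. Without 14A replicate 1 GDF15 differed by 0.19, and without 14A replicate 2 TP53I3 by -0.01 and GADD45A by -0.20. The p53 target lists did not pass (adjusted p = 0.169 for arrest, 0.775 for apoptosis and 0.187 for DNA repair and metabolism). Glycolysis and hypoxia genes were lower with 14A (median -0.09, 21 of 27 negative, 0 called, adjusted p = 0.0432, and adjusted p = 0.934 with an estimated correlation), with CA9 at -0.81 and PKM at -0.42. That list was lost without p53 replicate 1 (0.749), 14A replicate 2 (0.917), GFP replicate 1 (0.0639) or GFP replicate 2 (0.0503), and under normexp (0.0523), no filter (0.0709) and only the arrays compared (0.0549).

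Set against p47, 14A gave higher INPP5D, CYP4F2, CYP4F3 and GDF15. INPP5D was at least 17.1-fold higher (log2 5.90, SE 0.35, adjusted p = 0.00322), CYP4F2 at least 12-fold (adjusted p = 0.00957), CYP4F3 at least 5.54-fold (adjusted p = 0.0367), and GDF15 rose by 2.35 (SE 0.26, adjusted p = 0.0386), from 0.77 ± 0.06 to 3.12 ± 0.56 (SD, n = 2). KLHL30 was at least 6.69-fold, PLK5 at least 5.95-fold and PNLIPRP2, a pancreatic lipase relative, at least 2.40-fold higher (adjusted p = 0.0386 each). The calls of GDF15 and CYP4F3 were lost whichever array was left out, and that of INPP5D without either 14A array. Called in the opposite direction in p47 against GFP, the transcripts XLOC_007835, XLOC_009451 and XLOC_l2_010936 were at least 7.14-fold, 4.91-fold and 4.23-fold lower with 14A than with p47. In p47 against GFP they were at least 8.74-fold, 6-fold and 5.17-fold higher. They were well above background on the 2 p47 arrays only and were kept by the filter through them. Both comparisons use those arrays, so the opposite calls restate 1 observation.

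In total 13 genes passed for 14A against p47, 10 higher and 3 lower, where quantile scaling gave 10 and 6 and median scaling 10 and 7. With a block for the set 29 passed, 23 higher and 6 lower, among them 12 of the 13. FDXR stood at 1.36 (adjusted p = 0.0503), MDM2 at 1.16 (adjusted p = 0.166), CDKN1A at 0.93, BAX at 0.91, TP53I3 at 0.88, BBC3 at 0.65, FAS at 0.46, GADD45A at 0.41, IGF1R at 0.11 and SFN at 0.04, none of which passed. With the block FDXR (adjusted p = 0.0172) and VWCE (2.21, adjusted p = 0.0339, against 0.100) passed. Without p47 replicate 2 BAX gave 0.11 and BBC3 0.29, and without 14A replicate 2 CDKN1A gave 0.44 and GADD45A 0.10. The p53 target lists were higher, by medians of 0.257 for DNA repair and metabolism (adjusted p = 7.15e-07, 1 called), 0.407 for arrest and feedback (adjusted p = 4.86e-05, 1 called) and 0.276 for apoptosis (adjusted p = 0.00384, 0 called). Adjusted over the list alone, 4, 5 and 0 members were higher. The adjusted p = 0.187, 0.533 and 0.341 with an estimated correlation, and without 14A replicate 2 it was 0.242, 0.141 and 0.265 with the preset value. Glycolysis and hypoxia genes were lower (median -0.20, 22 of 27 negative, adjusted p = 4.86e-05), with SLC2A3 at -0.71 and ENO2 at -0.52. Cholesterol synthesis (median -0.16, adjusted p = 0.00900, MVD at -0.44 and HSD17B7 at 0.38), G2 and mitosis (median -0.08, adjusted p = 0.0132, CDC25C at -0.34 and NCAPG at 0.45) and interferon response genes (median -0.08, adjusted p = 0.0432, OAS1 at -0.84 and CMPK2 at 1.01) were also lower, with 0 members called in any. CMPK2 was well above background on 4 of the 8 arrays and OAS1 on 5. CMPK2 stood at -4.79 and -6.90 on the p47 arrays, against -4.53 and -5.15 with 14A. For the glycolysis, cholesterol, mitosis and interferon lists the adjusted p = 0.700, 0.934, 0.934 and 0.934 with an estimated correlation. Without 14A replicate 2, glycolysis gave 0.204 and cholesterol 0.682, which gave 0.478 without p47 replicate 1. Without 14A replicate 1, the mitosis and interferon lists gave 0.952 and 0.949, and without p47 replicate 2 they gave 0.569 and 0.475. Mitosis was also lost under quantile scaling (0.0742), and interferon under quantile (0.131) and median scaling (0.195), without a filter (0.106), with the strict filter (0.123) and with the mean of probes (0.0700). The 13 calls became 0 without either 14A array, 2 without either GFP array, 2 and 1 without p53 replicates 1 and 2, and 2 and 1 without p47 replicates 1 and 2.

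PROC, SH2D2A, LOC100129931 and the probe A_33_P3312754 were called in the same direction in all 3 comparisons against GFP. All 9 p53 calls were also called with 14A, where independent lists would share 0.00762 higher and 0.000523 lower. p53 and p47 shared 5 calls (0.00274 and 0.00139), and p47 and 14A shared 9 (0.00980 and 0.00418). With a block for the set the shared calls were 39, 28 and 28, in that order. In simulations that redrew all arrays, GFP included, with no group changed, comparisons sharing the simulated GFP arrays shared 0.04 to 0.06 calls on average and at most 1. With no gene changed, they cannot show how many of the shared calls found here come from the shared controls. With 2 GFP arrays the controls could not be split, so part of these overlaps may come from the shared controls. The fold changes of all genes had a covariance of 0.114 for p53 and 14A (0.0638 simulated), 0.0954 for p53 and p47 (0.0638 simulated) and 0.116 for p47 and 14A (0.0636 simulated), and correlations of 0.670, 0.608 and 0.609 against about 0.50 simulated. The shared calls depended on single arrays. Those of p53 and 14A became 4 without GFP replicate 2, 3 and 2 without p53 replicates 1 and 2, and 6 without 14A replicate 1, or 7 without 14A replicate 2 or either p47 array. Those of p53 and p47 became 2 without GFP replicate 2, 1 without either p53 array and 1 and 3 without p47 replicates 1 and 2. Those of p47 and 14A became 5 and 2 without GFP replicates 1 and 2, 3 without either p53 array, 1 and 2 without p47 replicates 1 and 2, and 2 and 3 without 14A replicates 1 and 2.

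The remaining lists passed in no comparison. Their lowest adjusted p was 0.545 for G1/S and DNA replication genes, 0.634 for the unfolded protein and integrated stress response, 0.22 for NF-kB and inflammatory genes, 0.635 for epithelial, 0.356 for mesenchymal and 0.491 for fibroblast markers, 0.366 for immediate early genes, 0.136 for cytosolic ribosomal proteins, 0.341 for housekeeping genes (medians of -0.05 to 0.08), 0.388 for p53 family and regulators, where CHEK2 gave 0.20 with p53, and 0.491 for the insulin-like growth factor pathway. Over the 6 comparisons, 18.3% to 35.1% of genes had groups that did not overlap, where chance gives 33.3% with 2 independent arrays against 2. That value, too, leaves out any variation shared by arrays of a set.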

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

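Array weights and the probe GC correction were chosen after seeing the data, and the other settings were planned. Leaving out an array leaves a lone array in its group, which is assumed to vary like the other groups. The calls of PROC in the 3 comparisons against GFP, of INPP5D with p53 and 14A, and of CYP4F2 and CYP4F3 with 14A, all against GFP, held under every setting that measured them and without each array, while no call of p47 against p53 or 14A against p47 did. The counts of genes passing (9, 25, 31, 2, 0 and 13 for p53, p47 and 14A against GFP, p47 and 14A against p53, and 14A against p47) moved by over 1.5 times as follows. With probes well above background on all arrays they were 2, 6, 7, 0 and, for 14A against p47, 0, where fewer genes are tested and transcripts dim in a group are left out. Without a filter they were 6 (p47 against GFP), 4 (p47 against p53) and 1 (14A against p53). With only the arrays compared they were 1 (p47 against GFP), 12 (14A against GFP), 0 (p47 against p53) and 1 (14A against p47), with fewer arrays to estimate the spread. Without an intensity trend they were 57, 50, 9, 6 and 32 in all but p53 against GFP. Robust empirical Bayes gave 15 in p53 against GFP, normexp 5 in 14A against p47, median scaling 14 in p47 against GFP and 6 in p47 against p53, and quantile normalization 7 in p47 against p53. Array weights gave 20, 117, 11, 7 (p47 against p53) and 1 (14A against p47). The weights came out equal within each pair (0.473 for both 14A arrays, 1.48 for GFP, 0.952 for p53, 1.5 for p47), so they could not single out an array. Without each array in turn the counts were 2 to 10, 2 to 21, 5 to 19, 0 to 3, 0 throughout, and 0 to 2. Rises and falls also shifted in share, leaving aside counts of 2 or fewer and arrays left out. In p53 against GFP (7 and 2) they were 6 and 5 without the trend or with GC correction, 12 and 8 with array weights, and 4 and 2 without a filter or with only the arrays compared. In p47 against GFP (9 and 16) they were 4 and 2 without a filter, in 14A against GFP (25 and 6) 35 and 15 without the trend, in p47 against p53 (0 and 2) 2 and 2 without a filter, 5 and 4 without the trend and 4 and 3 with array weights, and in 14A against p47 (10 and 3) 5 and 0 with normexp and 8 and 4 without a filter. The cause of the other movements was not tested.

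A block for the replicate number gave 47 (26 higher and 21 lower), 66, 81, 2, 0 and 29 calls. The labels do not say whether a set was a shared day or batch. ENST00000390551 lost its call in 14A against GFP (adjusted p = 0.0557) and XLOC_006905 in 14A against p47 (0.0508), and beyond these and the calls gained beside the results the block changed no call of a named gene or list. The calls shared with the block were 28 (p53 and p47), 39 (p53 and 14A) and 28 (p47 and 14A).

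Of the list tests 32 passed, 23 to 37 without each array, and 0 with an estimated correlation or with fry. Among single list tests under alternatives, 888 results stayed on their side of the threshold, 133 lost it and 48 gained it. Those that turned direction were p47 against p53 without p53 replicate 2, for oxidative phosphorylation (adjusted p 0.755, against 1.49e-04 without p53 replicate 1) and histones (0.679, against 9.01e-06). XLOC_006905 turned to -0.26 in 14A against p47 without a filter. Other gene results were the same in 4891 cases, lost the threshold in 654 and gained it in 45. Calls shared by p53 and p47 (5) were 8 with normexp or GC correction, 3 without a filter, 2 with the strict filter, 1 with only the arrays compared, 9 with robust empirical Bayes, 12 with array weights and 1 to 6 without each array. Those of p53 and 14A (9) were 2 with the strict filter, 14 with robust empirical Bayes and 2 to 9 without each array. Those of p47 and 14A (9) were 5 with median scaling, 3 without a filter or with the strict filter, 1 with only the arrays compared, 17 without the trend, 4 with array weights and 1 to 5 without each array. Signal over background limits what dim transcripts can show, since their folds are only lower bounds.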

Other observations

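The tests of second probes, the count of CA-rich probes among the falls and the test of p53 and p47 together were chosen only after the result was seen, as was the GC correction of the 14A arrays. Averaged over the 89 measured genes of the 3 p53 target lists, the arrays stood at 0.416 and 0.579 log2 units with p53, 0.0920 and 0.0401 with p47, and 0.519 and 0.637 with 14A, relative to the GFP mean. A hypothesis was that p47 weakens the effect of p53 on these genes. The effect was 0.498 without p47 (p53 against GFP) and 0.512 with it (14A against p47), a difference of 0.0145 (SE 0.104) that lay within 2 standard errors of 0 and so decided neither way. Taken within set 1 and set 2 it was 0.0235 and 0.00551, and with a block for the set its SE was 0.105. As set up, only a difference above 0 by more than 2 standard errors counted against weakening, so its absence could not be shown. A loss of the whole effect of 0.498 would lie beyond 2 standard errors from the difference found, which argues against it. A smaller weakening stays open. Both effects set arrays in slide columns 3 and 4 against arrays in columns 1 and 2, so column and p53 cannot be told apart in them. The amounts of each protein made from the plasmids were not measured.

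PROC, SH2D2A, LOC100129931 and the probe A_33_P3312754 shifted against GFP with all 3 other plasmids, and HSPA6, C8orf58 and LOC553137 were lower with p47 and 14A, with values of -3.17, -1.58 and -1.78 for p53 that did not pass (adjusted p = 0.0630 each, and 0.0106 for HSPA6 with a block for the set). The p53 and GFP arrays share a slide row, so the p53 differences are not differences between rows, while a part of row in those of p47 and 14A was not tested. The p47 and GFP arrays share slide columns, while a part of column in the differences of p53 and 14A was not tested. For HSPA6 an artefact of its probe is argued against by the second probe, at -1.72 on average. For C8orf58 and LOC553137 the other probes averaged 0.217, so hybridisation specific to the called probes is a candidate explanation, although the other LOC553137 probe was dim (-4.51 with GFP). Whether the GFP plasmid or a common effect of the other plasmids moved the first group stays open, as no array without a plasmid is in the design and the first 4 have no other kept probe. The same question is open for OR51B5 and HRH2, called only with 14A and only with p47, which were higher than GFP with all 3 plasmids. It is also open for KALRN, F7, LINC00955 and AK127601, called only with p47, which were lower than GFP with all 3 plasmids. The heat shock list was lower than GFP with all 3 plasmids. Between plasmids its list test did not pass (adjusted p = 0.892 for p47 against p53, 0.868 for 14A against p53 and 0.942 for 14A against p47).

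Probes with many CA repeats were common among the falls of p47 against GFP, at 8 of 16 against 0.536% of genes tested (two-sided Fisher exact p = 6.68e-15). A candidate explanation is a CA-rich transcript binding many probes. Among genes not called, the 149 CA-rich probes had a median of -0.23 with p47, and 0 of 10000 random probe sets of like signal reached it (percentile 0, with a 5th percentile of -0.09). The same probes had medians of -0.16 with p53 and -0.21 with 14A. The Fisher test and the random sets treat the probes as independent. If a shared transcript bound them, that would not hold, and both would overstate the evidence. An effect of p47 on each of these genes separately was not tested and stays open.

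The 14A arrays differed from each other with an SD of 0.708 across genes, above the other pairs (0.473 to 0.575). Correcting for probe GC content left it at 0.698 and quantile normalization at 0.697, both above the other pairs treated alike, which argues against either as the whole cause. Loss of signal away from the 3′ end is a candidate explanation, since the 5′ minus 3′ difference between the replicates had a median of -0.24, against -0.11 for GFP, 0.01 for p47 and 0.10 for p53. Both arrays carry the same labels, so no biological explanation was tested.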
